A study of Mus musculus with 4 samples.

How the data were processed

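The labels describe total RNA isolated with RNeasy columns and biotin-labelled cRNA made with the Ovation PicoSL kit (NuGEN), measured on a mouse whole-transcript array. The vehicle of heme was 0.15 M NaCl with 10% NH4OH, and the medium held 10% serum. The values are linear intensity after RMA, per the labels, which the authors ran before deposit. The files hold no background or detection call, so how far a low signal lies above background is unknown. The design text of the series describes sorted progenitors from fetal liver chimeras and another RNA kit, which does not match the sample labels, and the sample labels were followed. That text also names quantile normalization, which is a step of RMA, and the program ArrayStar, without a version, which may belong to other samples. No scaling was added. Values were taken to log2, and all comparisons are differences of log2 values between arrays.

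Of 35556 probe sets, the array annotation used here listed 23410 and did not list 12146. A single gene symbol stood at 21789 and several at 1621, and 21698 of the former had their Entrez number in the RefSeq gene table of assembly GRCm38.p6. No genome build came with the values, so no positions are given. Where a gene had several probe sets, as 999 did, the probe set with the highest mean over the 4 arrays was used, which left 19938 genes. Probe sets without a single gene were left out of the comparisons.

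The following choices were made before the data were examined. A gene counted as at level in a comparison when the brightest array compared reached the median of all values (log2 4.95). It counted as higher or lower at a 2-fold difference or more, with no p-value. The genes named in every comparison were Bach1, Spic, Hmox1 and Vcam1. Added to these were the 12 largest increases and the 12 largest decreases for both heme responses and for the knockout difference in vehicle, and 10 and 10 for the other comparisons. They had to be at level, 2-fold or more and of a single symbol, with predicted genes, microRNA, small nucleolar RNA, olfactory and vomeronasal receptor, clone and immune receptor segment names left out of naming but not of counts. From each list, the rule takes 2 to 4 members with the largest differences, and for several lists the text gives the median or percentile alone. Exceptions picked after their values were seen are marked where they stand.

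The 24 gene lists cover heme and iron handling with Bach1 targets, antioxidant and stress responses, metabolism, inflammation and markers of macrophages, dendritic cells and other cell types. They held 10 to 30 measured genes each, and some genes stand in more than 1 list. A further 48 list entries were not analysed here, among them Hba-a1, Hbb-bs, Gapdh, Isg15, Slc11a1 and G6pdx. List medians were taken over all measured members, and the 10000 random lists were drawn from genes in 20 bins of mean signal. Genes within 5 Mb of Bach1 were found by the midpoint of each gene, since the gene table gives no strand, although the design had named the transcription start.

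Correlations between comparisons that share an array were set beside those of 100 simulated sets of unchanged arrays with the same sharing. The alternatives were a 1.5-fold and a 3-fold rule, no level filter and a filter at the 75th percentile (a signal of 106), quantile normalization applied again, lowess centring of the log2 ratio on level, 32 added to each value before log2, the mean of a gene's probe sets, unmatched random lists, list members at level alone, Spearman correlation and windows of 2 and 10 Mb. Chosen after seeing the data were the correlation of mean responses and the lists of proteasome and MHC class II genes. In a simulation of the wild-type heme comparison, 99.0% of 100 genes changed by 3-fold were called in the right direction, and 2 of 10593 unchanged genes were called. Of 40 simulated lists of 20 unchanged genes, 2 lay outside the central 95%. The simulation took its noise from these arrays and has no culture-to-culture variation. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.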

Results

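The data were gene expression values from 4 microarrays of mouse bone marrow cells grown with GM-CSF, a growth factor under which marrow yields adherent macrophages and dendritic-type cells. Marrow from wild-type mice and from mice labelled as Bach1 knockouts, both on the B6 background, was cultured for 6 days with 20 ng/ml GM-CSF and then given heme at 40 µM (the labels write the unit with a lower-case m) or its vehicle. RNA came from the cells that still adhered 24 hours later. Bach1 is a transcriptional repressor that binds heme and is released from DNA by it, and the series' title names heme, Bach1 and the transcription factor Spic. Each of the 4 groups held 1 array, so no difference below has a replicate check, and no p-value or replicate error is given. The values were linear signals of 35556 probe sets per array. Median signals were 30.4 for wild-type vehicle, 30.9 for wild-type heme, 31.4 for labelled knockout vehicle and 31.1 for labelled knockout heme, and the brightest probe sets lay between 15150 and 16000. Log2 signals of any pair of arrays correlated across probe sets with r between 0.975 and 0.981.

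A gene was counted as higher or lower when 2 arrays differed by 2-fold or more and the brighter of them reached the median of all values, a signal of 30.96. The robust SD of single-gene log2 differences, which mixes technical noise with real differences, was between 0.25 and 0.28 in the comparisons of 2 arrays. Gene lists were described by their median log2 difference and its percentile among 10000 random lists of the same size and mean signal. Of the 120 placements of 24 lists in 5 comparisons, 51 lay outside the central 95% of random lists, where 6 would for lists of unrelated genes. Lists share genes and comparisons share arrays. Random lists were also drawn gene by gene, while genes of a real list can vary together and leave the range after any shift between 2 arrays. The 51 therefore describe these arrays and are no test of an effect.

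The Bach1 probe set read 212 in wild-type vehicle, 264 in wild-type heme, 211 in labelled knockout vehicle and 204 in labelled knockout heme. It did not separate the arrays by their genotype label. Where its probes lie relative to the deleted part of the gene is not given in the sources used here, so this signal checks nothing about the labels, and the arrays are called labelled knockout. The knockout difference stands for the labelled knockout minus wild type.

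**Figure D1:**
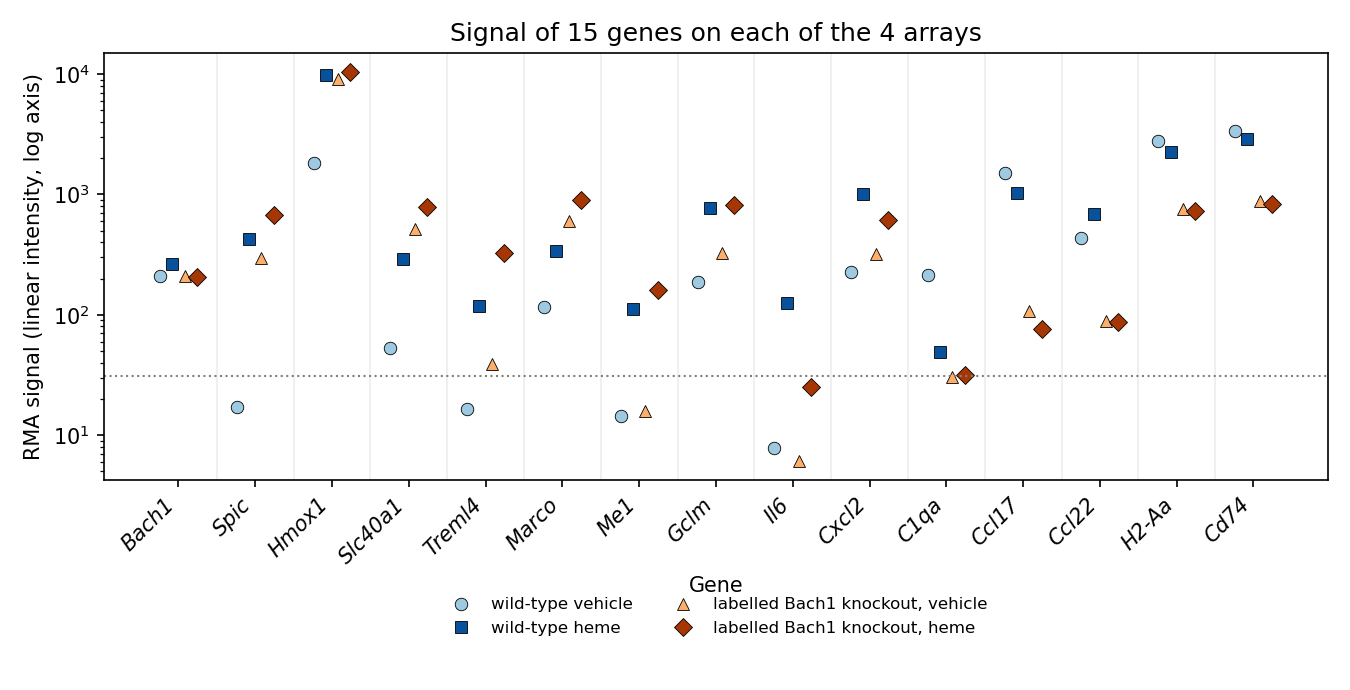
Signals (linear intensity, log axis) of 15 genes on each of the 4 arrays, 1 point per array; the dotted line is the level filter at 30.96. Spic lies at 17.0 on the wild-type vehicle array and between 298 and 679 on the others, while Ccl17 lies at 1520 and 1019 in wild type and at 107 and 76.0 on the arrays labelled knockout.

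The comparison of heme with vehicle in wild-type cells asks which genes respond to heme when Bach1 is present. Spic, a transcription factor required for red pulp macrophages of the spleen, had the largest difference: its signal was 17.0 in vehicle and 429 with heme, 25.2-fold higher. The vehicle value of Spic lay below the level filter. Hmox1, the enzyme that breaks heme down, read 1827 in vehicle and 9881 with heme (5.41-fold), the iron exporter Slc40a1 read 52.7 and 290 (5.50-fold), and the heme transporter Slc48a1 read 418 and 1113. The lists of inflammatory mediators and antioxidant enzymes were also higher, while the complement genes C1qa, C1qb and C1qc were lower. In all, 126 of 10772 genes at level were at least 2-fold higher and 96 at least 2-fold lower with heme, and 17 and 7 of them 4-fold.

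The 12 genes with the largest increase in wild type were, after Spic, the cytokine Il6, which was 16.0-fold higher, the malic enzyme gene Me1 (log2 difference 2.93), Treml4 (2.85), the itaconate-producing enzyme Acod1 (2.65), the IL-36 cytokine gene Il1f9 (2.62), Slc40a1 (2.46), Hmox1 (2.44), Layn (2.36), Tnfsf4, which encodes OX40 ligand (2.23), and the neutrophil-attracting chemokines Cxcl3 (2.21) and Cxcl2 (2.14). The largest decreases were those of Bex1 (-3.51), Ms4a7 (-2.61), the collagenase Mmp13 (-2.59), Qpct (-2.26), the growth factor Pdgfc (-2.15), C1qa (-2.12), Mamdc2 (-2.06), Slco2b1 (-1.90), C1qb (-1.83), Rgs1 (-1.79), Zfp580 (-1.77) and Emp1 (-1.77). Vcam1, a red pulp macrophage marker, read between 12.1 and 13.5 on all 4 arrays and never reached the level filter. Of the 24 named genes, 13 had folds over 1.5 times smaller with 32 added to each signal. The increase was then 9.40-fold for Spic, 3.93 for Il6, 3.08 for Me1, 3.10 for Treml4, 3.13 for Layn and 2.20 for Tnfsf4. The decrease was 3.37-fold for Bex1, 3.05 for Ms4a7, 3.98 for Mmp13, 2.60 for Qpct, 2.55 for Pdgfc, 2.25 for Slco2b1 and 1.99 for Zfp580, so that Bex1 no longer had the largest.

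Of the inflammatory mediators, 9 of 21 at level were 2-fold higher with heme in wild type and 0 lower, with a list median of 0.77 against a central range of -0.14 to 0.11 for random lists. The NRF2 antioxidant list had 7 of 28 higher and 0 lower (median 0.57), among them Me1, the glutathione synthesis gene Gclm (2.05), the quinone reductase Nqo1 (1.88) and the transporter Abcc1 (1.69). Neutrophil markers moved with the inflammatory genes: 4 of 15 at level were higher, namely Cxcr2 (1.60), Mmp9 (1.29), Retnlg (1.22) and Prtn3 (1.20), and the list median was 0.40. Macrophage core markers were lower as a list (median -0.23), with C1qa, C1qb, C1qc (-1.63) and the Fc receptor Fcgr1 (-1.51) among 6 of 22 at 2-fold. At these 4 genes the wild-type vehicle array alone stood 2-fold above every other array. Genes of cholesterol synthesis had the lowest median, -0.49, with Msmo1 (-0.90), Dhcr7 (-0.85) and Idi1 (-0.78) in front, and 0 of 20 reached 2-fold. Medians also lay above the random range for glycolysis and hypoxia genes (0.21), fibroblast and endothelial markers (0.18) and ribosomal proteins (0.09), and below it for lysosomal genes (-0.20) and dendritic cell and antigen presentation markers (-0.16). None of those 5 lists had more than 1 member 2-fold higher or 1 lower. Only 6 of the 16 fibroblast and endothelial markers were at level. Against random lists not matched on signal, the ribosomal proteins stood at percentile 91.7, inside the central range, and the respiratory chain at 1.11, outside it.

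The other 14 lists lay inside the range in wild type, with medians between -0.15 and 0.14. Of the Bach1 target and iron list, 4 of 22 genes were 2-fold higher, Slc40a1, Hmox1, Lcn2 (1.57) and Slc48a1 (1.41), and 1 was lower, the transferrin receptor Tfrc (-1.11), and the list stood at percentile 96.9 (median 0.11). Red pulp macrophage markers split: Spic, Treml4, Slc40a1 and Hmox1 were higher and 2 of the 10 at level lower, so that the median was -0.14 while the mean was 0.52. For erythroid markers (median 0.13, mean -0.02) and immediate early genes (median -0.05, mean 0.01) the median and the mean also differed in sign. Medians were 0.03 for heme biosynthesis, 0.12 for the heat shock response, 0.10 for the ER stress and amino acid response, -0.07 for the type I interferon response, -0.02 for the cell cycle, -0.15 for LXR targets, -0.04 for alternative activation, -0.15 for the respiratory chain, 0.14 for B, T and NK cell markers and -0.05 for mast cell and basophil markers. With 32 added to each value, 50 genes were higher and 37 lower, and 23 of the 24 named genes stayed at 2-fold or more, all but Zfp580.

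In cells labelled Bach1 knockout, the comparison of heme with vehicle asks which responses remain without a working Bach1 gene. Me1 was 10.0-fold higher (15.9 in vehicle, 160 with heme), Treml4 8.33-fold (39.3 and 328), Uchl1 5.88-fold, the glutathione transferase Gsta3 4.25-fold and the acute-phase gene Saa3 4.04-fold. Spic read 298 in vehicle and 679 with heme, 2.28-fold higher. Hmox1 read 9047 and 10330, 1.14-fold higher, and Slc40a1 read 512 and 787. Of 10843 genes at level, 130 were at least 2-fold higher and 49 lower, with 5 and 1 at 4-fold.

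The remaining genes among the 12 largest increases were Serpinb10 (1.96), Il1f9 (1.91), Clec2i (1.89), Layn (1.86), the proteasome ATPase genes Psmc2 (1.81) and Psmc5 (1.74), and Nol3 (1.80). The largest decreases were those of Bex1 (-2.14), Mamdc2 (-1.79), the hypoxia-inducible factor gene Epas1 (-1.77), Gask1b (-1.71), Mmp13 (-1.64), Phtf1os (-1.64), Ifi213 (-1.56), the inhibitor of DNA binding Id3 (-1.53), the neuropeptide Npy (-1.46), the arginine transporter Slc7a2 (-1.43), Ear6 (-1.39) and caveolin 1, Cav1 (-1.37).

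The NRF2 list again stood far above random lists with heme in the labelled knockout (median 0.63; 8 of 28 higher, 0 lower), with Gsta3 (2.09) and Abcc1 (1.34) beside Me1. Inflammatory mediators had a median of 0.28 and 4 of 21 at 2-fold, among them Saa3 (2.02), Acod1 (1.71) and Cxcl3 (1.13). Il6 (2.04) stayed below the level filter on both arrays and is not among the 4. Cholesterol synthesis genes had the lowest median, -0.53, and 4 of 20 were 2-fold lower: Fdps (-1.20), Idi1 (-1.11), Cyp51 (-1.07) and Hsd17b7 (-1.01). The heat shock list (median 0.27, with the chaperone Dnajb4 at 1.12 and Hsph1 at 0.95), the ER stress and amino acid list (0.19, with Mthfd2 at 1.37 and Slc3a2 at 1.07) and ribosomal proteins (0.15) also lay above the random range. Lists below it were erythroid markers (-0.28), glycolysis and hypoxia (-0.24), LXR targets (-0.24), alternative activation (-0.20, with Rnase2a at -1.32 and Arg1, arginase 1, at -0.95), cell cycle genes (-0.20), immediate early genes (-0.15), lysosomal genes (-0.12) and macrophage core markers (-0.11). Only 3 of the 11 erythroid markers were at level. Unmatched random lists put macrophage core markers at percentile 8.35 and lysosomal genes at 4.49, inside the range, and neutrophil markers at 97.6, outside it. At Serpinb10 and Mthfd2 the labelled knockout vehicle array alone stood 2-fold below every other array, and at Epas1 and Id3 it stood 2-fold above every other array.

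For 10 lists the median in the labelled knockout lay inside the random range, between -0.11 and 0.13. Neutrophil markers (median 0.13) had 0 of 16 members at 2-fold. Of the Bach1 target and iron list (median 0.02), the biliverdin reductase Blvrb (1.26) and the porphyrin transporter Abcb6 (1.20) were 2-fold higher. Red pulp macrophage markers had 2 of 10 higher, Treml4 (3.06) and Spic (1.19), with a median of -0.08 and a mean of 0.17. The type I interferon list also differed in sign between its median (-0.01) and mean (0.03). With 32 added to each value, Me1 was 4.01-fold higher, Treml4 5.04-fold, Uchl1 3.35-fold and Gsta3 2.53-fold, and Bex1 2.92-fold lower. The fold was over 1.5 times smaller for these and for Serpinb10, Layn, Nol3, Gask1b, Phtf1os, Ifi213 and Id3. In all, 58 genes were then higher and 14 lower, and 19 of the 24 named genes stayed at 2-fold; Serpinb10, Phtf1os, Ifi213, Id3 and Cav1 did not.

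**Figure D2:**
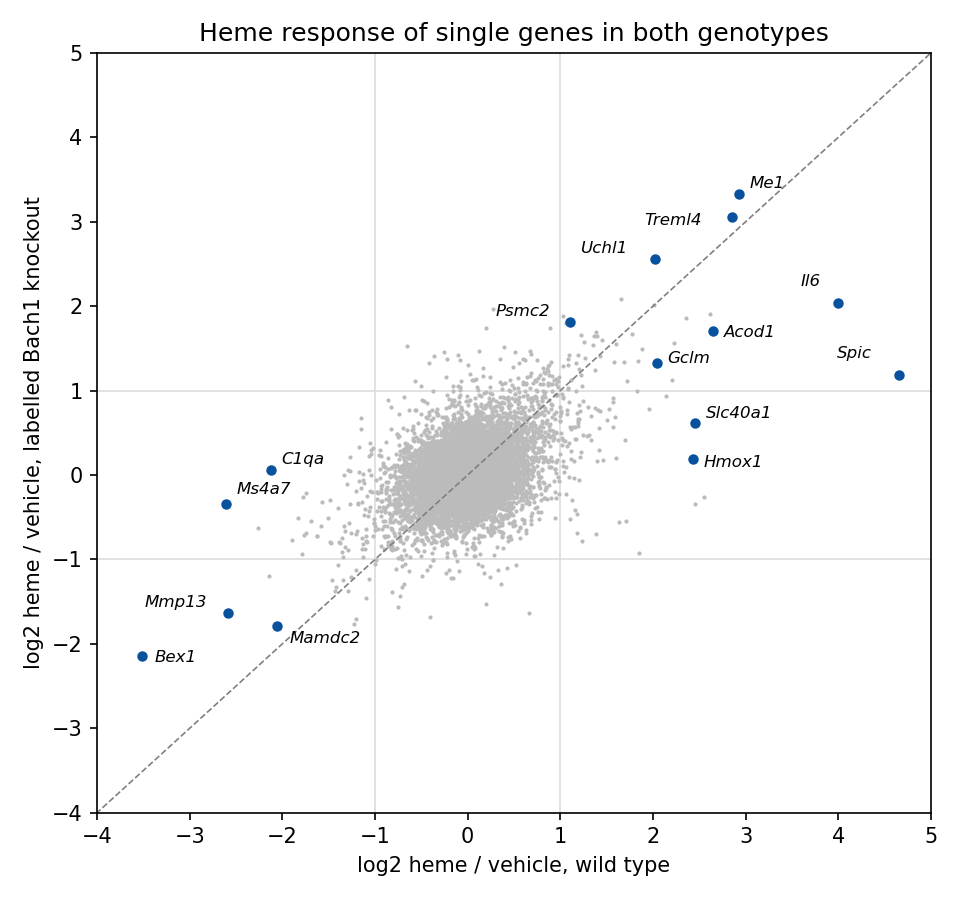
Log2 ratio of heme to vehicle in cells labelled Bach1 knockout (vertical axis) against the same ratio in wild type (horizontal axis), 1 point per gene for 11155 genes at level on any array; the dashed line marks equal responses and the grey lines 2-fold. Me1 and Treml4 lie near the dashed line, and Spic, Slc40a1 and Hmox1 lie well to its right.

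The arrays labelled knockout and wild type were next compared in vehicle, which asks what the loss of Bach1 does without added heme. Spic was 17.5-fold higher on the array labelled knockout (17.0 and 298), Slc40a1 9.71-fold (52.7 and 512), the scavenger receptor Marco 5.24-fold (115 and 605), and Hmox1 4.95-fold (1827 and 9047), and the nitric oxide synthase Nos2 read 24.4 and 97.8. The chemokine Ccl17 was 14.2-fold lower (1520 and 107) and Ccl22 4.92-fold lower (438 and 89.1). Genes of antigen presentation by MHC class II were lower together: Cd74, the invariant chain, read 3399 in wild type and 877 in the labelled knockout. Of 10859 genes at level, 57 were at least 2-fold higher and 124 at least 2-fold lower, with 4 and 12 at 4-fold.

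Other named increases were Cib3 (1.82), Fam110c (1.72), Cenpw (1.59), Rgs1 (1.51), Plpp3 (1.49), Cdc42bpa (1.43) and the neutrophil gene Retnlg (1.36). The named decreases after Ccl17 were C1qa (-2.80), the semaphorin Sema6d (-2.49), Plbd1 (-2.43), C1qc (-2.42), Ccl22 (-2.30), Klk1b9 (-2.20), Hepacam2 (-2.19), the Fc receptor-like gene Fcrls (-2.15), Plet1 (-2.14), Kmo (-2.10) and Flrt3 (-2.09).

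Dendritic cell and antigen presentation markers had the lowest list median in vehicle, -0.76 (random range -0.12 to 0.10), and 11 of 20 at level were 2-fold lower, with H2-Eb1 at -1.96 and Cd74 at -1.95. Over the 20 members at level alone, the median was -1.09. The alternative activation list had a median of -0.35, with 5 of 16 lower and 1 higher. It shares Ccl17, Ccl22, Irf4 and Cd209a with the dendritic cell and antigen presentation list. Its 2-fold lower genes included Ccl17, Ccl22, the lectin Mgl2 (-1.69) and Pdcd1lg2, which encodes PD-L2 (-1.55). Inflammatory mediators had a median of -0.34, with Marco and Nos2 2-fold higher against Ccl2 at -0.99 and Il1b at -0.81. Cholesterol synthesis (-0.23) and the respiratory chain (-0.18) were also below the random range. The Bach1 target and iron list lay above it (median 0.17; 3 of 22 higher), with Slc40a1, Hmox1 and Slc48a1 (1.02) at 2-fold. Also above it were glycolysis and hypoxia (0.25, with Ankrd37 at 1.20), cell cycle (0.16), neutrophil markers (0.14; 1 of 16 higher), NRF2 (0.10; 0 of 25 at 2-fold) and lysosomal genes (0.05, with Marco at 2.39). Unmatched random lists put NRF2 at percentile 93.3, neutrophil markers at 96.7 and lysosomal genes at 73.4, each inside the range. In 13 lists the median lay inside the range. Of these, macrophage core markers had 4 of 22 lower, C1qa, C1qc, C1qb (322 and 80.7) and Fcgr1 (-1.48), with a median of 0.04 and a mean of -0.35. These 4 differences, like the heme response of the same genes in wild type, use the wild-type vehicle array. It stood 2-fold above every other array at each of these genes. With heme in both cultures, a comparison without that array, C1qc was also 2-fold lower in the labelled knockout (295 and 103). C1qa (48.9 and 31.9), C1qb (90.6 and 56.9) and Fcgr1 (83.3 and 59.7) were lower there by less than 2-fold. The wild-type vehicle array stood 2-fold below every other array at Spic, Slc40a1, Hmox1, Slc48a1, Marco, Nos2, Treml4 and Retnlg. Red pulp macrophage markers had 4 of 10 higher and 1 lower (median 0.07). Immediate early genes stood at percentile 2.75, with Nr4a3 at -1.32 and Fosb at 1.28, and at 0.54 among unmatched lists. Medians and means differed in sign for fibroblast and endothelial markers (0.00 and -0.08), the type I interferon response (0.03 and -0.04) and the ER stress and amino acid response (0.01 and -0.05). With 32 added to each value, Spic was 6.73-fold higher, Slc40a1 6.42-fold and Nos2 2.30-fold, and C1qa 3.91-fold and Sema6d 3.22-fold lower. The fold was over 1.5 times smaller for these and for Cib3, Fam110c, Cenpw, Hepacam2, Kmo and Flrt3. In all, 16 genes were then higher and 56 lower, and 17 of the 24 named genes stayed at 2-fold, all but Cib3, Fam110c, Cenpw, Retnlg, Hepacam2, Kmo and Flrt3.

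With heme in both cultures, the difference between genotypes at Hmox1 was 1.04-fold and at Spic 1.58-fold, both higher on the array labelled knockout, while the antigen presentation genes stayed apart. Hmox1 read 9881 and 10330, at percentile 99.96 of the labelled knockout heme array. A ceiling of the signal can therefore not be told apart from equal expression at Hmox1. Ccl17 was 13.4-fold lower (1019 and 76.0) and Ccl22 7.93-fold lower (686 and 86.4), and Il6 was 4.91-fold lower (124 and 25.3). Slc40a1 was 2.72-fold higher (290 and 787), Marco 2.62-fold and Treml4 2.77-fold. Of 10790 genes at level, 56 were at least 2-fold higher and 105 lower, with 3 and 10 at 4-fold.

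The other named increases were Rgs1 (2.36), Bex1 (2.13), Klra2 (1.56), the complement regulator Cd59a (1.52), Rgs2 (1.36), the fatty acid binding protein Fabp7 (1.35) and the Fc receptor Fcgr4 (1.34). The named decreases included the nuclear receptor Nr4a3 (-2.49), Klk1b9 (-2.20), Ccn3 (-2.15), Sema6d (-2.04), Csta3 (-1.99), Jaml (-1.92) and H2-Eb1 (-1.92). Inflammatory mediators had the lowest median, -0.54, and 7 of 21 were 2-fold lower, with Acod1 at -1.49 and Ccl5 at -1.34, against Marco, which was higher. At Il6, Acod1, Cxcl3 and Csta3, and at the neutrophil marker Cxcr2, the wild-type heme array alone stood 2-fold above every other array. At Rgs1 and Bex1 it stood 2-fold below every other array. The labelled knockout heme array alone stood 2-fold above every other array at Treml4 and Abcb6, and 2-fold below at Ccn3. Dendritic cell and antigen presentation markers followed (-0.53; 9 of 20 lower; -0.88 over the members at level), then alternative activation (-0.40; 4 of 15 lower), immediate early genes (-0.27), cholesterol synthesis (-0.26), fibroblast and endothelial markers (-0.21), glycolysis and hypoxia (-0.19) and neutrophil markers (-0.14, with Cxcr2 at -1.22). Only 6 of the 16 fibroblast and endothelial markers were at level. Red pulp macrophage markers (0.18) and lysosomal genes (0.14) were the 2 lists above the random range, with 2 of 10 and 1 of 25 members 2-fold higher. The other 14 lay inside it, with medians between -0.16 and 0.11, the Bach1 target and iron list among them (0.11), with 2 of 23 members 2-fold higher, Slc40a1 and Abcb6. The respiratory chain had a median of -0.01 and a mean of 0.05. With 32 added to each value, Il6 was 2.73-fold lower, Nr4a3 2.44-fold, Sema6d 2.20-fold and Jaml 2.43-fold. The fold was over 1.5 times smaller for these and for Bex1, Cd59a and Csta3. In all, 12 genes were then higher and 49 lower, and 17 of the 20 named genes stayed at 2-fold, all but Bex1, Cd59a and Csta3.

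**Figure D3:**
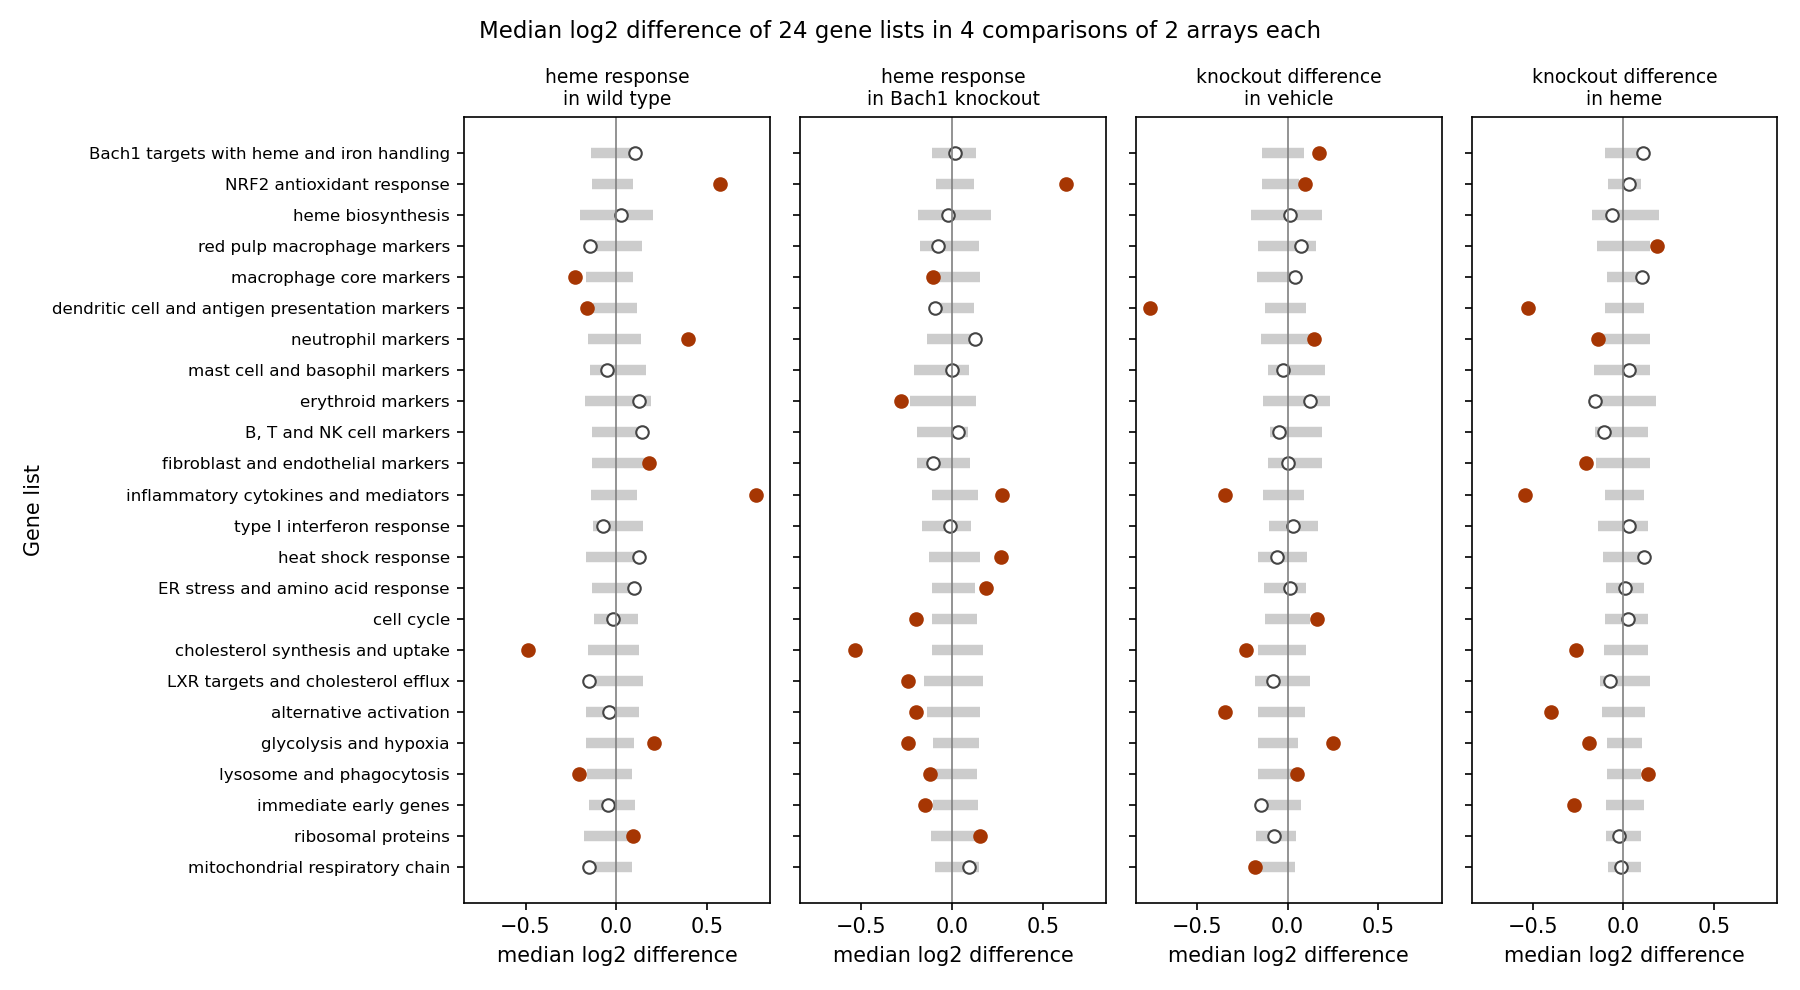
Median log2 difference of 24 gene lists (rows) in the 4 comparisons of 2 arrays (panels); grey bars span the central 95% of 10000 random lists matched on signal, filled points lie outside it and open points inside. The NRF2 list lies at 0.57 and 0.63 in the heme responses, and the dendritic cell and antigen presentation list at -0.76 and -0.53 in the knockout differences.

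The wild-type heme response minus that of the labelled knockout uses all 4 arrays and carries the noise of each (robust SD 0.32). Spic had the largest value, 3.47 on the log2 scale, Hmox1 reached 2.24, Nos2 2.25, Il6 1.96 and Slc40a1 1.84, each with the larger heme response in wild type. C1qa (-2.18) and Ms4a7 (-2.26) were 2-fold lower with heme in wild type and not in the labelled knockout. There C1qa read 30.6 in vehicle and 31.9 with heme, near the level filter of 30.96, so a missing decrease cannot be told from a signal already low. Ms4a7 read 64.1 and 50.3. Of 11155 genes at level on any of the 4 arrays, 98 had a difference of 2-fold or more toward a higher response in wild type and 130 toward a lower one. With 32 added to each value, Spic had a difference of 2.13 and Nos2 of 1.38, while Hmox1 had 2.22, above that of Spic. The fold was over 1.5 times smaller for 15 of the 20 named genes, among them Rny1 (1.04), Phtf1os (1.01), Ms4a7 (-1.39) and Polr2k (-1.19). The counts were then 21 and 13, so that the higher side held more genes, and 11 of the 20 named genes stayed at 2-fold. The 9 below it were Cib3, Id3, Senp8, Myo1d, Adgre4, Zfp931, Serpinb10, Ciart and Mterf4.

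The other named genes in this difference were Rny1 (2.78), Phtf1os (2.30), Cib3 (2.01), Id3 (1.73) and Ppp4r2 (1.65) on the higher side, and Polr2k (-2.19), Senp8 (-1.82), Myo1d (-1.75), Adgre4 (-1.72), Zfp931 (-1.70), Serpinb10 (-1.69), Ciart (-1.68) and Mterf4 (-1.64) on the lower. A second, dimmer probe set gave -0.39 for Myo1d and -0.66 for Ciart. At Id3, Myo1d and Serpinb10 the labelled knockout vehicle array alone stood 2-fold apart from every other array. Lists above the random range were inflammatory mediators (median 0.39; 4 of 22 at 2-fold, Nos2, Il6, Cxcl2 at 1.20 and Cxcl3 at 1.08), glycolysis and hypoxia (0.29), neutrophil markers (0.26; Cxcr2 at 1.40 and Prtn3 at 1.26) and immediate early genes (0.12, at percentile 92.7 among unmatched lists). Macrophage core markers (-0.28; 3 of 22 at 2-fold) and the respiratory chain (-0.20) lay below it. The other 18 lists lay inside, including NRF2 (0.02), cholesterol synthesis (0.00) and dendritic cell and antigen presentation markers (-0.05). Red pulp macrophage markers (median -0.18, mean 0.35), heme biosynthesis (median -0.15, mean 0.06) and alternative activation (median -0.07, mean 0.03) had medians and means of opposite sign.

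The heme responses of the 2 genotypes share no array. Across 11155 genes at level, which are not independent replicates, they correlated with Pearson r = 0.43 and Spearman rho = 0.32. They shared 44 genes at 2-fold higher, where independent lists would share 1.36, and 16 lower, where 0.33 would be shared, with 0 genes in opposite directions. Shared higher genes included Me1, Treml4, Spic, Gclm, Nqo1, Sqstm1, Sod2, Acod1, Saa3, Psmc2 and Clec4e, and shared lower genes Bex1, Mmp13, Mamdc2, Pdgfc, Epas1, Cav1 and Npy; of these, Sqstm1, Sod2 and Clec4e were picked after their values were seen. Of the 126 genes higher in wild type, 111 had a positive difference in the labelled knockout, with a median of 0.76 against 1.22 in wild type. Of the 130 genes higher in the labelled knockout, 116 had a positive difference in wild type, with a median of 0.82 against 1.23 in the labelled knockout. Picking genes by their size in 1 pair of arrays lowers the median in the other. The 2 knockout differences also share no array (r = 0.36) and had 53 genes lower in both, where 1.02 would be shared by independent lists, and 13 higher, where 0.22 would be. In opposite directions, Phtf1os was higher in vehicle and lower in heme, where 0.43 genes would be shared, and Ms4a7 and Polr2k lower and higher, where 0.52 would be. Slc40a1, Marco, Treml4 and Rgs1 were among the 13, and Ccl17, Ccl22, Cd74, H2-Aa, H2-Ab1, H2-Eb1 and Ciita among the 53; H2-Aa, H2-Ab1 and Ciita were picked after their values were seen.

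The wild-type heme response and the knockout difference in vehicle, which ask together whether heme resembles the loss of Bach1, share the wild-type vehicle array. They correlated with r = 0.34, while unchanged arrays simulated with the same sharing gave 0.50. That simulated r is fixed by the shared array and by equal noise on all arrays. An r below it therefore shows no lack of resemblance. The covariance was 0.045 against 0.026 in the simulation, whose noise came from these arrays and can hold real differences. The knockout difference in heme shares the wild-type heme array with opposite sign. With it, r was -0.33, with -0.50 simulated and fixed in the same way, and the covariance -0.040 against -0.026. A relation in which the shared arrays cancel if all carry equal noise was added after seeing the data. It set the mean heme response against the mean knockout difference and gave r = -0.01. Equal noise could not be checked with 1 array per group, so this r does not decide whether heme resembles the loss of Bach1. At 2-fold, heme in wild type and the knockout difference in vehicle had 16 higher genes in common, where independent lists would share 0.33, among them Spic, Hmox1, Slc40a1, Slc48a1, Treml4, Marco, Nos2, Retnlg and Cenpw. They had 15 lower genes in common, where 1.12 would be shared, among them C1qa, C1qb, C1qc, Fcgr1, Fcrls, Ms4a7, Qpct and Sema6d. Both overlaps include what the shared array adds, which was not separated, so independent lists are no reference for a lack of relation here. The pair had 2 genes lower with heme and higher in the labelled knockout, Epas1 and Rgs1. With the knockout difference in heme, 20 genes were higher with heme in wild type and lower in the labelled knockout, and 10 the reverse. Overlaps in opposite directions are built in there by the shared wild-type heme array and show no relation by themselves.

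Genes within 5 Mb of Bach1, where DNA of another strain can remain beside a targeted allele, were compared with all others. In vehicle, the 36 neighbours at level had a median knockout difference of -0.07, and 0 were 2-fold higher and 1 lower, Tiam1 at -1.41, named after its value was seen. In heme, the 35 neighbours had a median of -0.05 and 0 reached 2-fold.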

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

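All tests of explanations in this part were chosen after the results were seen. Probe sets without a single gene, which no comparison above uses, carried signal differences with heme in wild type. Of 6774 such probe sets at level, 512 were 2-fold higher (7.56%) and 311 lower, 3 and 6 of them with several gene symbols. In the labelled knockout 441 were higher and 246 lower, and 92 of the 512 were among the 441. Of the genes used above, 126 of 10772 at level were higher in wild type, and 44 of the 126 were also higher in the labelled knockout. The unnamed probe sets thus differed more often and carried over less often. Each gene was counted by its brightest probe set, which was not done for unnamed probe sets, so the counts are not fully alike. No explanation was tested.

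Spic, Hmox1 and Slc40a1 had smaller folds with heme in the labelled knockout (2.28, 1.14 and 1.54) than in wild type (25.2, 5.41 and 5.50), from higher vehicle signals; with 32 added, the folds of Spic were 2.15 and 9.40. Against a ceiling of the array for Spic and Slc40a1 stands that the wild-type fold would need signals of 7509 and 2812 on the labelled knockout heme array, where 67 and 529 probe sets read higher. That test replaced an earlier one that left the question open (Spic and Slc40a1 at most at percentile 93.8 in labelled knockout vehicle, with 17 genes from their level up 2-fold higher with heme), and a ceiling of their own probe sets was not tested. For Hmox1 the needed signal is 48920, above all signals of that array, so a ceiling cannot be told apart from a smaller response. A single deviating wild-type vehicle array could also give the pattern: it stood 2-fold apart from every other array at 30 genes, these 3 and C1qa, C1qb, C1qc and Fcgr1 among them, against 26 or fewer for each other array, and the genotype itself stays open and untested without replicates.

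Antigen presentation genes were lower on both arrays labelled knockout, with medians of -1.56 in vehicle and -1.43 in heme for 8 MHC class II and invariant chain genes listed after seeing the data. Scaling that depends on signal is argued against, since after lowess the weaker of the 2 medians was -1.44. Of the 11 antigen presentation list members 2-fold lower in vehicle, 0 lie within 5 Mb of Bach1, so they are not themselves genes of that flanking stretch. The window held 0.33% of genes at level, so a count of 0 would be likely for any set of that size. It decides nothing further about flanking DNA, and an effect through a flanking gene stays open. Fewer dendritic cells among the adherent cells may contribute and cannot be told apart from lower expression per cell. The 11 dendritic cell markers at level outside the MHC class II genes, Ccl17 and Ccl22 had a median of -0.46 in vehicle. They ran from -1.53 for Cd86 to 0.68 for Clec9a. Ccl17 (-3.83) and Ccl22 (-2.30), left out of these 11, were lower still. The genotype stays open and untested, since there was 1 array per genotype and treatment, and the labels do not say how many cultures each held.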

How the results depend on the processing

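No paired analysis was possible because the labels pair no samples, and with 1 array per group no array could be left out. Counts of genes at least 2-fold higher or lower are given for heme in wild type, heme in the labelled knockout, the knockout difference in vehicle, that in heme and the difference of heme responses, in this order. At 1.5-fold, 537, 545, 353, 365 and 574 genes were higher and 509, 333, 468, 370 and 699 lower. At 3-fold, 32, 20, 9, 5 and 18 were higher and 17, 7, 35, 28 and 15 lower. With 32 added to each value, 50, 58, 16, 12 and 21 were higher and 37, 14, 56, 49 and 13 lower. With the filter at the 75th percentile, 82, 23, 20 and 25 were higher (heme in the labelled knockout stayed within 1.5 times) and 55, 24, 80, 68 and 31 lower. Without a level filter, 181 genes were higher in the difference of heme responses. For these fold rules and filters the move follows from their construction. Adding 32 to each value makes every fold between 2 arrays smaller, most at low signals. The fall of the counts in the comparisons of 2 arrays therefore also follows from its construction. For the difference of heme responses the cause was not tested. The other 40 counts, which include both other scalings and the mean of probe sets, stayed within 1.5 times. Against unmatched random lists, ribosomal proteins (91.7), for heme in wild type, and macrophage core markers (8.35) and lysosomal genes (4.49), for heme in the labelled knockout, came to lie inside the central range. So did NRF2 (93.3), neutrophil markers (96.7) and lysosomal genes (73.4) in the vehicle difference and immediate early genes (92.7) in the difference of heme responses. The respiratory chain (1.11, heme in wild type), neutrophil markers (97.6, heme in the labelled knockout) and immediate early genes (0.54, vehicle difference) came to lie outside, and the cause was not tested. Over members at level, the dendritic cell and antigen presentation medians were -1.09 in vehicle and -0.88 in heme, and in heme those of mast cell and basophil (-0.41) and B, T and NK cell markers (0.39) rested on 1 gene each; the other 596 recomputed medians moved little. The correlation of heme responses was 0.30 without a filter and 0.32 by Spearman, and the cause was not tested. At 1.5-fold, the heme responses shared 200 higher and 110 lower genes, and heme in wild type shared 87 and 114 with the vehicle difference. The other results stayed on the same side or moved little: 110 list percentiles, 8 counts of shared genes, 6 correlations of heme with the knockout difference and 4 medians of Bach1 neighbours. Of the values of single named genes, 199 moved and 345 did not with 32 added, 3 moved with the mean of probe sets, and 0 with the other scalings. No value called 2-fold changed sign under an alternative. Low signals limit the precision of large folds, since their height above background is unknown.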

Other observations

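All tests in this part, and both proteasome lists, were chosen after the results were seen. Genes of the 26S proteasome, the complex that degrades ubiquitin-tagged proteins, were higher with heme in both genotypes. Of 31 subunit genes at level, 8 were 2-fold higher in wild type (median log2 difference 0.82, 30 above 0) and 21 in the labelled knockout (median 1.16, 31 above 0), and 0 were 2-fold lower. Psmc2 read 1.81 and Psmc5 1.74 in the labelled knockout. Subunits of the immunoproteasome and its activators, 5 genes, had medians of 0.00 and 0.16. Between genotypes 0 of the 26S genes differed by 2-fold, but their median knockout differences, -0.16 in vehicle and 0.16 in heme, each lay outside the central range of random lists. After lowess the vehicle median was -0.11, within the range of -0.15 to 0.03 found without lowess, and the heme median was 0.15. The wild-type heme response minus that of the labelled knockout had a median of -0.30.

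A common response of the 26S genes to heme that does not need Bach1 is a hypothesis found on these arrays. Scaling that depends on signal is argued against, since the smaller of the 2 medians was 0.87 after lowess. A rise of every proteasome-related gene is argued against by the immunoproteasome and activator genes, whose larger median was 0.16. The genotype labels could not be checked by the Bach1 signal, and there was 1 array per group, so a difference between cultures that goes with heme stays open.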
